A study of Mus musculus with 12 samples.

How the data were processed

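RNA-seq was done on 4 mouse embryonic stem cell lines: 2 wild-type lines, WT-1 and WT-2, and 2 lines named Mut-1 and Mut-2, whose label gives the genotype as Tin2 S341X. Per the labels' protocols the cells came from C57BL/6 blastocysts and were grown in serum and LIF on mouse embryonic fibroblast feeders, and total RNA was taken from these cultures, so feeder RNA can be in every library. The series' design text calls the 3 libraries of each line technical replicates, which gave 12 libraries.

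The deposited values are whole-number counts of reads per gene, not normalized by the authors, with 1 column per library. The submitters' processing notes name bcl2fastq, Bowtie2 2.2.3, HISAT2 2.1.0, HTSeq 0.6.0 and the genome build GRCm38. Their roles, the gene annotation and the strand setting are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart, and the counts of near-identical gene copies are uncertain. A table of transposable elements that the labels mention is not analysed here.

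The table holds 31641 gene symbols. For positions, symbols were matched to GENCODE M21 on GRCm38, the build the submitters' notes name. By name 29383 symbols matched and by an older symbol 187, so that 29570 had a position. Of the others, 2022 did not match and 49 had several loci. Library totals ran from 14766477 to 17891894 counts. The genes detected per library ranged from 22713 to 24070, and the 10 most abundant genes took between 5.99% and 6.94% of the counts.

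Because the design text calls the libraries of a line technical replicates, the line was taken as the unit of replication for the genotype. Counts of the 3 libraries were summed per line, and the 2 mutant lines were compared with the 2 wild-type lines with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, edgeR's filterByExpr and Benjamini-Hochberg adjustment at 0.05. Line totals ran from 47284654 to 52074216 counts. Pairs of lines (Mut-1 with WT-1, Mut-2 with WT-2, WT-2 with WT-1, Mut-2 with Mut-1) were compared in 1 edgeR fit of the 12 libraries with 4 line groups, at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. The p-values of these pairs measure only the spread between the libraries of a line, which is not the spread between independent lines. CPM values are TMM-normalized, and a mean ± SD with n = 2 is over the line totals of a genotype.

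Before the data were examined, 28 gene lists with 698 symbols were fixed, among them markers of feeder fibroblasts, blood cells, endoderm, neural and other cell types. Of these symbols 8 were not in the table. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation and with fry. The feeder share is the percentage of a library's counts on the feeder list, compared by an exact permutation test over the 4 lines, which cannot give a p below 0.333.

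Genes to be named were set by a rule written before the data were examined. In each direction it took 12 genes of mean CPM of at least 2 with the largest fold change among those past the threshold. Where fewer than 12 passed, it was filled with the largest fold changes among genes in which each of the 6 mutant libraries lay beyond each of the 6 wild-type libraries. It added Tinf2, up to 4 members of each list by smallest p, and 5 genes per direction for each pair of lines. Predicted genes were counted but passed over for the next symbol. Designs, tests, lists and most alternatives were chosen before the data were examined; the analyses by chromosome and the alternatives said to be added were chosen afterwards.

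For the shifts by chromosome, log2(CPM + 0.5) of genes with a mean of at least 5 CPM and a position was centred over the 12 libraries. The median over a region's genes was then taken relative to the median of the other autosomes. These are medians over genes, not tests over lines. Start points of the shifted ends of chromosomes 5 and 10 were placed where a single step in Mut-1 left the smallest residual sum of squares.

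WT-1 replicates 1 and 2 were far closer to each other than other libraries of a line: the chi-square of their counts per degree of freedom was 1.66, against 12.0 to 42.5 for the other pairs within lines. They still differed by more than sampling noise, so both stayed in the line total. In a mean ± SD within WT-1 they were counted as 1 sample. Libraries of different lines could be as close as other libraries of 1 line, such as WT-1 replicate 3 and WT-2 replicate 3 at 10.8. Technical replicate is therefore used here only as the design text's name for the libraries of a line. Same-number libraries deviated together (each correlation of deviations from the line means over 0.1) between the wild-type lines, at 0.114 to 0.485, between the mutant lines, at 0.176 to 0.429, and between WT-2 and Mut-1, at 0.18 to 0.352. By this rule the numbers pair the libraries of these comparisons. This pairing comes from the data and not from the labels. It is not exact, since WT-1 replicate 1 reached 0.235 with WT-2 replicate 2, against 0.114 with WT-2 replicate 1. The main counts use no replicate block, which was run as an alternative.

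The alternatives tried were DESeq2 1.42.0, RLE normalization, other filters, the 12 libraries as independent samples, limma-voom on the 12 libraries with line as a random block, with and without the feeder share as a covariate, a replicate block, the line number as a block, and lines and libraries left out. With 1 line left out, a single line is compared with 2, and the spread is that of the 2 lines. The fit of line totals, the comparison of Mut-1 with WT-1 and the limma fit were tested on simulated data in which 100 genes were changed 2-fold and 100 genes 4-fold. With line totals, over 18448 genes fitted, 79.0% of the 2-fold and 100% of the 4-fold changes were recovered, and 15 unchanged genes were called. These counts were drawn from each gene's estimated spread, without the further gene-wise spread that the quasi-likelihood test allows for. In the data Rhox5, at a log2 fold change of -2.13, had an adjusted p of 0.102 in this edgeR test. The recovered shares thus do not show that changes of this size are absent from the data. For Mut-1 against WT-1, over 16307 genes fitted, these shares were 40.0% and 96.0%, with 7 unchanged genes called. The 2-fold changes sat at the fold change minimum of this comparison. Their median absolute log2 estimate was 0.982, so many failed by that rule. The limma fit recovered 92.0% and 98.0% and called 19 unchanged genes. In the simulated 12 libraries the lines of a genotype had the same mean, with the spread within lines alone. These false calls thus do not show how the fits act when lines of a genotype differ. In the data the limma fit's correlation within lines was estimated at -0.00251, so the random block had almost no weight and the libraries counted as nearly independent.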

Results

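RNA-seq counts were analysed from mouse embryonic stem cells, pluripotent cells taken from the blastocyst, that carry or lack an altered Tinf2 gene. Tinf2 encodes TIN2, a subunit of the shelterin complex that binds telomeres. The series asks what TIN2 deficiency does to telomere maintenance by recombination (ALT) and to differentiation. There were 2 wild-type lines, WT-1 and WT-2, and 2 mutant lines, Mut-1 and Mut-2, with 3 libraries each. WT-1 libraries held 17211009, 16971313 and 17891894 counts, and WT-2 libraries 16013579, 17106437 and 15127354. Mut-1 libraries held 15702083, 14766477 and 16816094 counts, and Mut-2 libraries 16504142, 16138574 and 15251613.

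Tinf2 was lower in every mutant library than in every wild-type library. It lies on the minus strand of chromosome 14 at 55674689 to 55681820 (GRCm38), and the serine named in the genotype label is encoded in exon 7 of 9 of transcript Tinf2-201, at 55679924 to 55679926. Replicates 1, 2 and 3 had 69.1, 64.8 and 57.6 CPM in WT-1 and 63.9, 58.7 and 60.5 CPM in WT-2. They had 29.7, 25.2 and 20.1 CPM in Mut-1 and 30.1, 27.4 and 19.6 CPM in Mut-2. The line totals gave 62.7 ± 2.22 CPM in wild type and 25.5 ± 0.939 CPM in the mutants (SD, n = 2 lines each), a log2 fold change of -1.30 (SE 0.11). With edgeR on the line totals the adjusted p was 0.0652, the smallest of the 18749 genes tested and above the threshold. Across libraries Tinf2 passed in both pairs of lines, with an adjusted p of 0.00297 for Mut-1 against WT-1 and 0.00911 for Mut-2 against WT-2 (edgeR). Without the 3 libraries of highest feeder share, an alternative added after the data were seen, 1 Mut-2 library was left, and the pair of line number 2 had a larger log2 fold change of -1.65 that did not pass (adjusted p = 0.0656). Leaving out 1 line gave Tinf2 an adjusted p of 0.0163 without WT-1, 0.532 without WT-2, 0.0175 without Mut-1 and 0.00466 without Mut-2 on the line totals. Each of these fits sets 1 line against 2, so its spread comes from the 2 lines of 1 genotype alone, and passing or not passing in it is no test over lines of both genotypes.

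**Figure D1:**
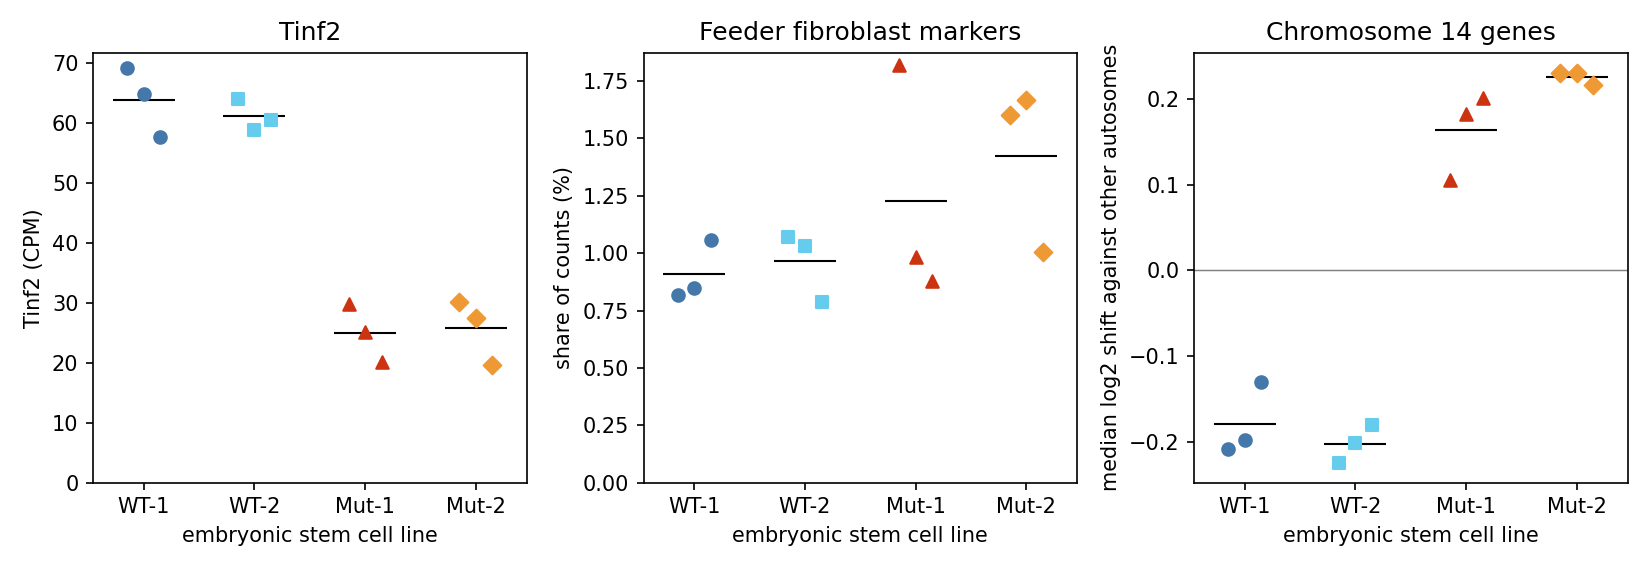
Each point is 1 library and each bar the mean of the 3 libraries of a line. The left panel plots Tinf2 in CPM, the middle panel the percentage of counts on feeder fibroblast markers and the right panel the median log2 shift of 398 chromosome 14 genes against other autosomes. Tinf2 lay between 57.6 and 69.1 CPM in wild-type and between 19.6 and 30.1 CPM in mutant libraries, and the chromosome 14 shift was above 0 in the mutant libraries alone.

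The genotypes were compared first by the genes with the largest differences among those whose mutant and wild-type libraries did not overlap. Aox3, an aldehyde oxidase, was at 7.01 ± 0.0996 CPM in the mutants and 1.89 ± 0.345 CPM in wild type. The transcription factors Foxd1 (6.80 ± 1.03 against 2.37 ± 0.0565 CPM), Sox6 (log2 fold change 1.37, SE 0.25) and Mecom (4.76 ± 0.402 against 1.92 ± 0.0895 CPM) were also higher. So were Spry2, an inhibitor of receptor tyrosine kinase signalling, at 209 ± 27.5 against 89.5 ± 2.98 CPM, and Shisa2, at 30.7 ± 1.79 against 13.2 ± 0.680 CPM (SD, n = 2 lines throughout). Nell2, Xkr6, Tie1, Kcnh7, Uggt2 and Cpm completed the 12 higher genes, whose log2 fold changes ran from 1.18 to 1.89. Xkr6, Spry2, Shisa2 and Uggt2 lie on chromosome 14.

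Among lower genes, the X-linked homeobox gene Rhox5 had 1.37 ± 0.0111 CPM in the mutants and 6.03 ± 1.88 CPM in wild type. Stag3, a meiotic cohesin subunit, was at 29.4 ± 0.718 against 50.6 ± 6.12 CPM. Hormad1, which acts on meiotic chromosome axes, was at 16.4 ± 2.33 against 26.6 ± 0.898 CPM. Hsf2bp, which acts in meiotic recombination, was at 39.4 ± 1.13 against 70.8 ± 5.59 CPM. Apela, a secreted peptide ligand of the apelin receptor, was at 7.32 ± 0.455 against 13.3 ± 0.332 CPM. Plvap, Liph, Eda2r, Srl, Ccdc155 and Ctnnal1, with Tinf2, completed the 12 lower genes.

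None of these 24 genes passed the edgeR test of line totals, which called 0 of 18749 genes. At an unadjusted p under 0.05 it had 1719 genes higher and 728 lower, 2447 in all, where chance gives 937. Of 13192 genes with at least 2 CPM, 199 were higher and 120 lower in each mutant library than in each wild-type library. A random order of 12 independent libraries gives 0.108% in each direction. If only the 4 lines are independent, their 4 values separate in 16.7% of random orders in each direction. Separation of all 12 libraries asks for more, so 16.7% is only its upper limit and no expected count was computed. On the same line totals DESeq2 called 295 genes higher and 65 lower, and edgeR with RLE normalization called Tinf2 alone. With limma-voom on the 12 libraries and line as a random block, 194 genes rose and 39 fell in the mutants, among them 11 of the 12 higher and 11 of the 12 lower genes above. The exceptions were Tie1 (adjusted p = 0.0507) and Ccdc155 (adjusted p = 0.122). All 24 genes were chosen for full separation of these same 12 libraries, so their calls in this fit are no separate support. The correlation of libraries within lines was estimated at -0.00251, so this fit in effect took the 12 libraries as independent samples, and its p-values do not measure the spread between lines. With the feeder share as a covariate this fit called 39 higher and 2 lower genes, and without the 3 libraries of highest feeder share, an alternative added after the data were seen, 14 higher and 1 lower. On line totals, edgeR called 53, 0, 158 and 92 genes without WT-1, WT-2, Mut-1 and Mut-2, each time with 1 genotype left as a single line. It called 96 without Mut-1 replicate 3, 11 without Mut-2 replicate 3, and 0 to 2 without any other single library.

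**Figure D2:**
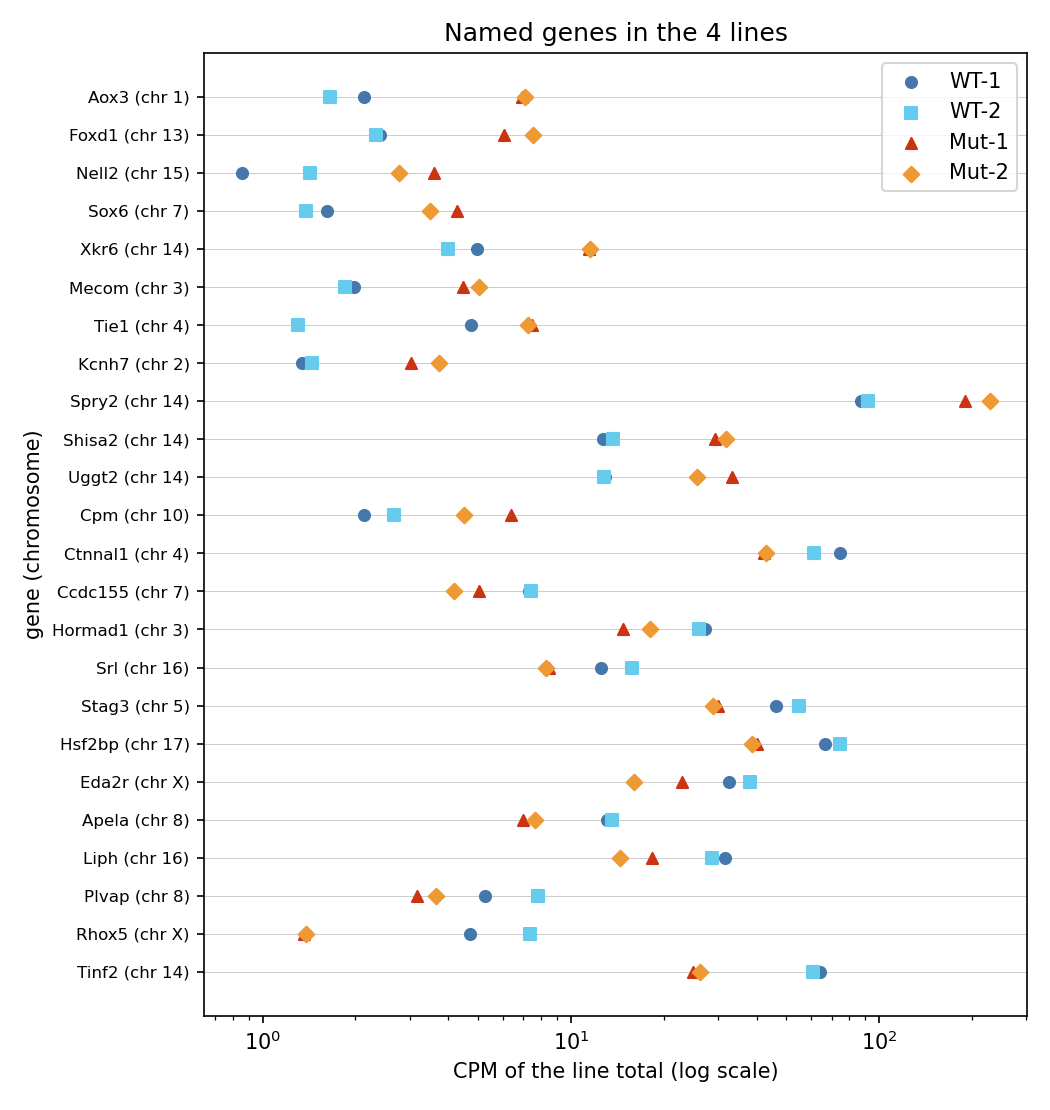
The 24 named genes, each in 1 row with its chromosome, against the CPM of the line total on a log axis, with 1 symbol per line. The genes were chosen for separate mutant and wild-type libraries, so both mutant lines lie on the same side of both wild-type lines by rule. An example is Spry2, at 190 and 229 CPM in the mutant lines and 87.4 and 91.6 CPM in wild type.

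Genes of chromosome 14, which carries Tinf2, were higher as a whole in both mutant lines. This chromosome was singled out after its values were seen. Over 398 genes the median shift against other autosomes was 0.35 (log2) in Mut-1 and 0.45 in Mut-2 relative to the wild-type lines, 1.32-fold for the mean of both, and 388 of the 398 genes (97.5%) were higher. The shift was between 0.11 and 0.23 in the 6 mutant libraries and between -0.23 and -0.13 in the 6 wild-type libraries. In no one of 10000 random lists of the same size and expression was the median as high. Of the 192 genes with a position that rose in the limma fit, 95 lay on chromosome 14, which holds 540 of the 16200 tested genes with a position (Fisher's exact test, odds ratio 34.2, two-sided p = 2.33e-89). Genes are not independent replicates, and with an estimated correlation camera gave the chromosome an adjusted p of 0.436, against 1.27e-35 at the preset correlation. Without chromosome 14 genes the limma fit called 40 genes higher and 16 lower. In the full limma fit 1 of the 38 lower genes with a position lay on chromosome 14, yet 39 lower genes became 16. The refit also repeats the normalization and the adjustment, so the fall is not that of the removed genes alone.

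Shifts of other regions followed single lines. Chromosome 8 genes were higher in WT-2 than in WT-1, by a median of 0.18 (log2) over 620 genes. At the end of chromosome 5, 74 genes from 140724127 onward (GRCm38) were higher in Mut-1 than in the other lines by a median of 0.74, while the 669 genes before this point differed by 0.01. On chromosome 10, 145 genes from 93831555 onward were higher in Mut-1 by 0.30, and the 395 before it by 0.01.

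**Figure D3:**
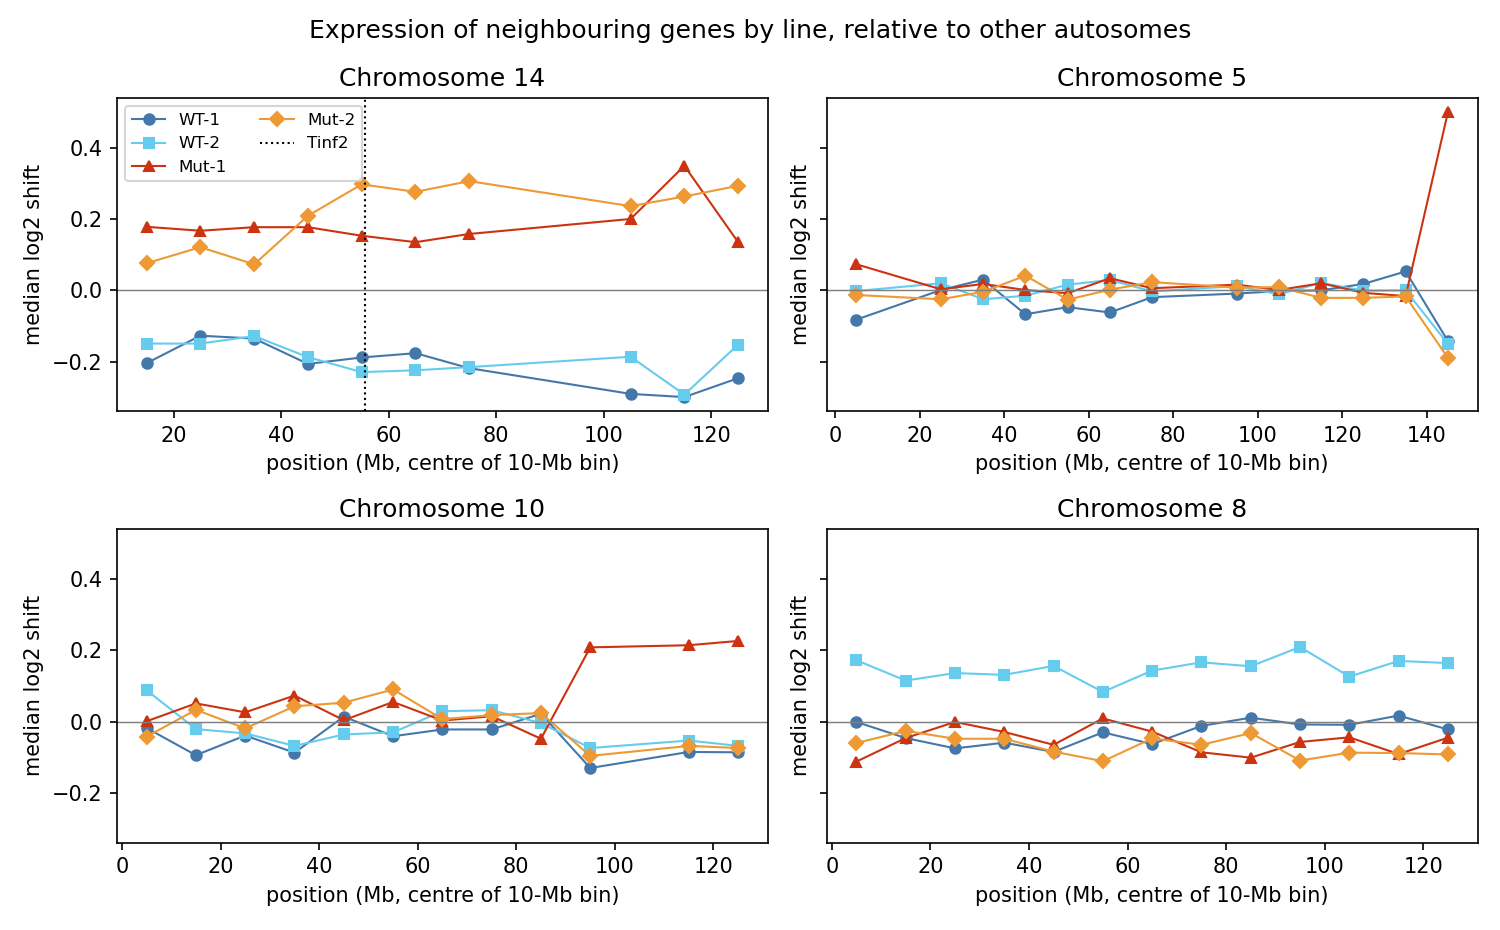
Median log2 shift of the genes in each 10-Mb bin relative to other autosomes, against position in Mb, with 1 line of symbols per cell line. Bins with under 10 genes are left out and the dotted line marks Tinf2. Both mutant lines lie above both wild-type lines along chromosome 14, Mut-1 stands apart at the ends of chromosomes 5 and 10, and WT-2 along chromosome 8.

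Markers of feeder fibroblasts were higher in the mutants, and 3 of the 6 mutant libraries carried more of them than any wild-type library. The feeder share was 0.936% ± 0.040 of the counts in wild type and 1.33% ± 0.14 in the mutants (SD, n = 2 lines), a difference with an exact two-sided permutation p of 0.333, the smallest that 2 lines against 2 allow. Mut-1 replicate 1 had 1.82% (95% Wilson interval 1.81% to 1.83%), Mut-2 replicate 1 had 1.60% (1.60% to 1.61%) and Mut-2 replicate 2 had 1.67% (1.66% to 1.67%). The highest wild-type library, WT-2 replicate 1, had 1.07% (1.07% to 1.08%). These intervals cover counting error only. All 35 measured markers were higher in the mutant lines (camera adjusted p = 2.14e-31, but adjusted p = 0.354 with an estimated correlation). The collagen Col3a1 had 204 ± 8.67 against 119 ± 4.73 CPM, Postn 168 ± 3.31 against 102 ± 0.916 CPM and Ctgf 553 ± 29.5 against 347 ± 15.7 CPM. Adjusted over the list alone 33 markers passed in edgeR, and 0 over all genes. Whether these counts come from feeder cells or from the stem cells themselves was not tested. The mean share was 0.945% in WT-1, 0.964% in WT-2, 1.23% in Mut-1 and 1.42% in Mut-2. As a covariate the feeder share can therefore also remove a difference between the genotypes.

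Genes of the 2-cell stage, which a small fraction of embryonic stem cells transcribes at any time, had the largest median difference of the 28 lists, and a similar difference lay between the wild-type lines, with a median of -1.12 for WT-2 against WT-1. Of 31 measured genes 30 were higher in the mutants, with a median log2 fold change of 1.19 (camera adjusted p = 7.39e-18, but adjusted p = 0.368 with an estimated correlation). Adjusted over the list alone 16 passed, and 0 over all genes; the limma fit called 5. The median relative to the mean of the lines was -0.01 in WT-1, -1.25 in WT-2, 0.45 in Mut-1 and 0.77 in Mut-2. Gm8300 had 5.22 ± 0.579 CPM in the mutants against 2.03 ± 1.03 CPM in wild type, and Arg2 1.43 ± 0.0851 against 0.444 ± 0.278 CPM. Gm2056 had 1.76 ± 0.322 against 0.526 ± 0.190 CPM, and B020004J07Rik 0.462 ± 0.0309 against 0.110 ± 0.0188 CPM. Most of the list's genes belong to families of near-identical copies, so the counts of single members are uncertain.

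Interferon and nucleic-acid sensing genes were higher in the mutants for 30 of 31 members, with a median log2 fold change of 0.65 (camera adjusted p = 3.65e-12, but adjusted p = 0.385 with an estimated correlation). The list's median relative to the mean of the lines was -0.505 in WT-1, -0.047 in WT-2, 0.124 in Mut-1 and 0.503 in Mut-2. By these medians WT-2 lay closer to Mut-1 than to WT-1. The ubiquitin-like modifier Isg15 had 34.7 ± 8.70 against 15.5 ± 2.32 CPM. Irf9, which carries the interferon response to the nucleus and lies on chromosome 14, had 56.0 ± 7.31 against 33.4 ± 0.231 CPM. Both rose in the limma fit across technical replicates (adjusted p = 0.0232 and 0.0257). Adjusted over the list alone 9 members passed in edgeR, and 0 over all genes. Of the 6 mutant libraries 3 also had a higher feeder share than any wild-type library. In the limma fit with the feeder share as a covariate the list was also higher (adjusted p = 9.41e-07), with a median log2 fold change of 0.53, against 0.66 without the covariate.

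Hox genes were higher for 27 of 29 members (camera adjusted p = 1.28e-06, but adjusted p = 0.366 with an estimated correlation). Hoxc10 had a log2 fold change of 1.05 (SE 0.25). Endoderm genes were higher for 17 of 19 (adjusted p = 1.12e-05, but adjusted p = 0.354 with an estimated correlation), with Gata4, on chromosome 14, at 14.1 ± 2.34 against 8.50 ± 1.53 CPM and the basement membrane chain Col4a2 at 187 ± 32.6 against 132 ± 5.20 CPM. The limma log2 fold change of Col4a2 was 0.44, and -0.01 with the feeder share as a covariate. With the feeder share as a covariate Hox genes had an adjusted p of 0.0201 and endoderm genes of 0.207. Their median log2 fold changes in the limma fit were 0.22 and 0.12 with the covariate, against 0.64 and 0.36 without it. Without the 3 libraries of highest feeder share both were called (adjusted p = 0.0349 and 0.0243). Camera also called the feeder list there (adjusted p = 0.000909), so leaving out these libraries does not remove the feeder difference. Adjusted over the list alone 0 Hox and 5 endoderm genes passed, and 0 of either over all genes.

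Lysosome and autophagy genes were higher for 17 of 21 (adjusted p = 0.000119, but adjusted p = 0.354 with an estimated correlation). The protease Ctsb, on chromosome 14, had 659 ± 62.6 against 420 ± 15.0 CPM and rose in the limma fit (adjusted p = 0.00529). Neural genes were higher for 13 of 18 (adjusted p = 0.00851, but adjusted p = 0.354 with an estimated correlation). The neurofilament genes Nefl, at 20.7 ± 2.76 against 11.8 ± 1.77 CPM, and Nefm, at 5.63 ± 1.66 against 2.87 ± 0.0356 CPM, lie on chromosome 14. The neural list was not called without chromosome 14 genes (adjusted p = 0.0649) or without Mut-2 (0.134). Genes of the mitochondrial genome (13 of 14 higher, adjusted p = 0.0257, but adjusted p = 0.62 with an estimated correlation) and blood and macrophage markers (8 of 9, adjusted p = 0.0313, but adjusted p = 0.366 with an estimated correlation) were the remaining higher lists. The mitochondrial list was not called without WT-2 (adjusted p = 0.377) or Mut-2 (0.0754), and the blood list not without Mut-2 (0.0702) or with the feeder share as a covariate (0.104). Adjusted over the list alone 7 lysosome genes were higher and 1 lower, 1 neural gene was higher, and 0 of the last 2 lists passed.

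The lists that were lower in the mutants served proliferation, recombination and metabolism, with small fold changes. DNA replication genes were lower for 36 of 38, with a median log2 fold change of -0.25 (camera adjusted p = 5.18e-13, but adjusted p = 0.354 with an estimated correlation). The licensing factor Cdc6 had 52.5 ± 1.71 against 72.7 ± 3.52 CPM, and Pola2, a subunit of DNA polymerase alpha, 98.9 ± 0.918 against 130 ± 1.15 CPM. In the limma fit the list's median was -0.25, and -0.10 with the feeder share as a covariate (adjusted p = 0.00329), where Cdc6 went from -0.45 to -0.21. Without the 3 libraries of highest feeder share the list had an adjusted p of 0.0348. Mitosis genes were lower for 21 of 23 (adjusted p = 9.06e-06, but adjusted p = 0.354 with an estimated correlation), and the checkpoint gene Mad2l1 fell in the limma fit (81.0 ± 5.67 against 104 ± 0.307 CPM, adjusted p = 0.0452). Genes of DNA methylation and heterochromatin were lower for 27 of 30 (adjusted p = 3.09e-05, but adjusted p = 0.354 with an estimated correlation). Among them the maintenance methyltransferase Dnmt1 had 285 ± 1.58 against 354 ± 1.44 CPM.

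Genes of recombination and ALT, the route of telomere maintenance in the series' title, were lower for 28 of 32 (median log2 fold change -0.14, camera adjusted p = 0.000104, but adjusted p = 0.366 with an estimated correlation). Asf1b, a histone chaperone, had 23.4 ± 0.405 against 34.2 ± 3.86 CPM, and the helicase gene Blm 92.6 ± 3.96 against 117 ± 0.0431 CPM. Both fell in the limma fit (adjusted p = 0.0498 and 0.0473). Glycolysis and hypoxia genes were lower for 21 of 25 (adjusted p = 9.00e-05, but adjusted p = 0.508 with an estimated correlation), with Pdk1 at 105 ± 6.99 against 148 ± 23.1 CPM. Their medians were 0.18 in WT-2 and 0.00 in WT-1, and without WT-2 the list was not called (adjusted p = 0.113). Oxidative phosphorylation genes were lower for 21 of 24 (adjusted p = 0.00851, but adjusted p = 0.368 with an estimated correlation), and not called without Mut-1 (adjusted p = 0.0519). With the feeder share as a covariate this list and that of DNA methylation were not called (adjusted p = 0.776 and 0.123). Adjusted over the list alone 0 members of any of these 6 lists passed in edgeR. Without the 3 libraries of highest feeder share the ALT, DNA methylation, mitosis and oxidative phosphorylation lists were no longer called (adjusted p = 0.104, 0.168, 0.234 and 0.535), while the formative and Wnt target lists were called (adjusted p = 0.000909 and 0.0369).

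The other shelterin and telomerase genes, listed without Tinf2, were not called as a list (13 of 17 lower, camera adjusted p = 0.132) except without Mut-2 (adjusted p = 0.0369), but Terf1, which encodes the shelterin subunit TRF1, stood apart from Tinf2. It had 146 ± 2.53 CPM in the mutants against 85.5 ± 7.82 CPM in wild type, a log2 fold change of 0.77 (SE 0.11). Terf1 passed adjusted over the list alone in edgeR (adjusted p = 0.00203) and rose in the limma fit across technical replicates (adjusted p = 0.00368), but did not pass over all genes on line totals (adjusted p = 0.102). The telomerase gene Tert had 17.5 ± 0.916 against 21.6 ± 2.18 CPM.

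Camera did not call the lists of naive and formative pluripotency or of epidermal, mesoderm and trophoblast genes. Naive pluripotency genes had an adjusted p of 0.237, formative and primed genes of 0.421, epidermal of 0.824, mesoderm of 0.235 and trophoblast of 0.687. Leaving out 1 line, which leaves 1 genotype without replicate lines, changed some of these calls: without WT-2 naive and formative genes were called (adjusted p = 0.00322 and 0.00354), and epidermal genes were called higher without Mut-2 (0.0138) and lower without Mut-1 (0.00749). In the fit without WT-2 naive genes were lower and formative genes higher. With the feeder share as a covariate formative genes were called higher too (adjusted p = 0.034). Of the 21 formative genes measured 4 lie on chromosome 14. With chromosome 14 genes left out, camera gave the formative list the direction lower and did not call it (adjusted p = 0.729). Single members did move in edgeR adjusted over the list alone. Utf1, a pluripotency chromatin factor, was lower (117 ± 18.2 against 179 ± 4.25 CPM, adjusted p = 0.0238). Klf5, on chromosome 14, was higher (173 ± 11.2 against 122 ± 1.79 CPM, adjusted p = 0.0238). Of the epidermal genes 3 were higher, among them Grhl2 (log2 fold change 0.84, SE 0.20, adjusted p = 0.0259), and 1 was lower, Tfap2c (-0.55, SE 0.12, adjusted p = 0.0259). The p53 targets (adjusted p = 0.421), germline methylation-sensitive genes (0.552, 20 higher and 9 lower, with Rhox5, Stag3 and Hormad1 among its members), imprinted genes (0.15), Wnt targets (0.396), Y-linked genes (0.552), X-inactivation genes (0.421) and senescence and apoptosis genes (0.14) were not called either. Y-linked genes were called higher without WT-1 (adjusted p = 0.000165) and lower without WT-2 (0.00569). The p53 targets were called without Mut-1 (0.0152), germline genes without WT-2 (0.00716) or Mut-1 (0.0397), and imprinted genes without WT-2 (0.0412). Among imprinted genes Grb10, a growth-restraining adaptor, rose in the limma fit (155 ± 25.5 against 88.5 ± 15.2 CPM, adjusted p = 0.0358). For the trophoblast and germline lists the median, mean and test did not share 1 sign.

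**Figure D4:**
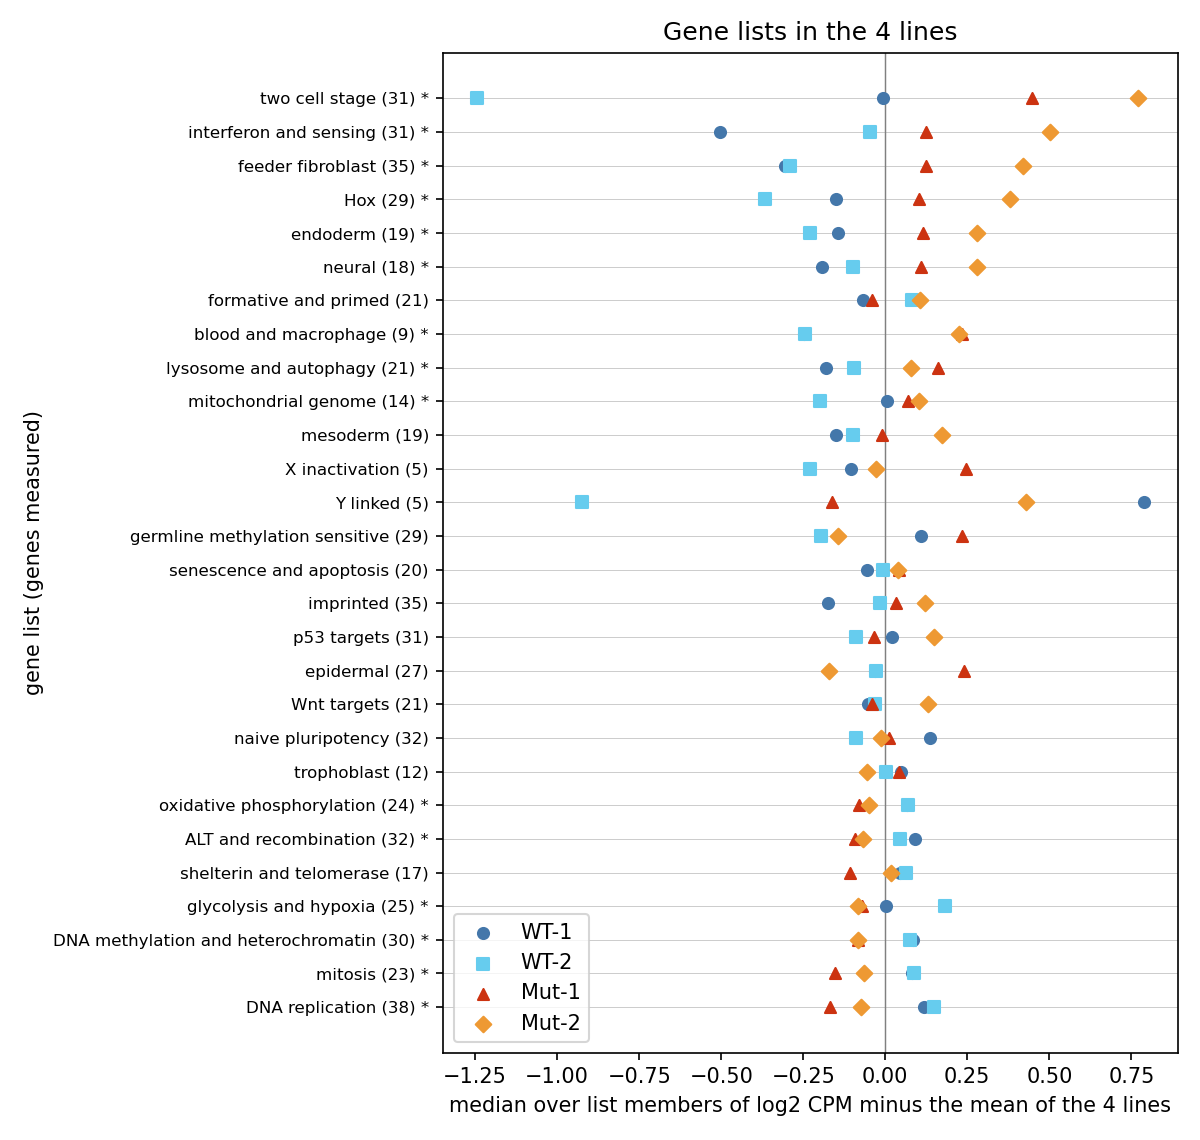
Each row is 1 of the 28 gene lists with its number of measured genes, and each symbol the median over its genes of log2 CPM in 1 line minus the mean of the 4 lines. An asterisk marks the 15 lists called by camera at the preset correlation, none of which was called with an estimated correlation. The 2-cell list spans from -1.25 in WT-2 to 0.77 in Mut-2.

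Within line number 1, Mut-1 differed from WT-1 by a group of genes at the end of chromosome 5 and by genes on other chromosomes. In the edgeR fit of the 12 libraries 29 genes rose and 5 fell of 16533 tested. Of the 29, 12 lay on chromosome 5 beyond 140724127, 4 on chromosome 14, 2 at the end of chromosome 10 and 1 on chromosome 8. Without the genes of these shifted regions, an alternative added after the data were seen, the count of 34 became 5. Of the 34 called genes 10 higher and 4 lower ones lay elsewhere, so the refit also lost calls outside the removed regions. Nxf3, on the X chromosome, rose by a log2 fold change of 4.27 (SE 0.34). The Hedgehog effector Gli1, at the end of chromosome 10, had 42.5 ± 4.72 CPM in Mut-1 (SD, n = 3 libraries) against 13.1 ± 4.58 CPM in WT-1 (n = 2). Capn11, Nell2 and Aox3 rose by log2 fold changes of 2.43, 2.07 and 1.72. The X-linked genes Xlr4a (log2 fold change -2.28) and Xlr5a (-1.53), the Y-linked gene Uty (-2.04) and Tinf2 (-1.35) fell. For Capn11 and Uty, WT-2 lay near Mut-1. Capn11 had 7.08 CPM in Mut-1 and 7.75 CPM in WT-2, against 1.44 CPM in WT-1. The line totals of Uty were 1.74 CPM in Mut-1, 1.51 CPM in WT-2 and 7.23 CPM in WT-1. With WT-1 replicates 1 and 2 averaged the count was 12, and leaving out WT-1 replicate 3 gave 208. Leaving out WT-1 replicate 1, WT-1 replicate 2, Mut-1 replicate 2 or Mut-1 replicate 3 gave 13, 13, 13 and 12.

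Within line number 2, 66 genes rose and 10 fell in Mut-2 against WT-2, and 13 of the 66 were 2-cell-stage genes on the fixed list, against 0 of the 29 in line number 1. The difference between the line numbers had a camera adjusted p of 5.70e-20 for this list, but adjusted p = 0.121 with an estimated correlation. Zscan4c had a log2 fold change of 2.36 (SE 0.36). Zscan4f had 3.76 ± 1.21 against 0.897 ± 0.389 CPM and Tmem92 9.51 ± 3.48 against 2.13 ± 0.802 CPM (SD, n = 3 libraries). Zscan4 genes are active at the 2-cell stage and in telomere elongation, and the counts of their near-identical copies are uncertain. The endothelial receptor gene Tie1 (log2 fold change 2.47) and Aox3 (7.08 ± 2.84 against 1.64 ± 0.336 CPM) also rose. Rhox5 (-2.41), Cpne9 (-1.75), Phf19 (-1.29), Gpc3 (-1.26) and Eda2r (-1.25) fell. The count was 1 without the 3 libraries of highest feeder share, which leaves 1 Mut-2 library whose spread is taken from the other lines. Leaving out WT-2 replicate 1, WT-2 replicate 3 or Mut-2 replicate 2 gave 14, 10 and 9 genes, against 76. From only the 6 libraries of these 2 lines edgeR called 11 genes, and DESeq2 on the 12 libraries called 209.

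Both pairs of lines shared 4 genes that changed the same way. Aox3, Spry2 and Shisa2 rose and Tinf2 fell in both, where independent lists would share 0.116 higher and 0.00302 lower genes (Fisher's exact test, one-sided p = 0.000206 and 0.00302). The 1 shared lower gene is Tinf2, the gene altered in both mutant lines, so the p-value of 0.00302 tells nothing of other genes. Spry2 and Shisa2 lie on chromosome 14, whose genes were higher together in both mutant lines. Genes are not independent, and this expectation and its p-values do not allow for that shared shift. The log2 fold changes of Spry2 were 1.15 (SE 0.20) in line number 1 and 1.32 (SE 0.20) in line number 2, and those of Shisa2 1.23 (SE 0.22) in both. Crossing the pairs gave 6 shared genes. Without the 3 libraries of highest feeder share, which leaves 1 Mut-2 library, 0 were shared, with log2 fold changes of Tinf2 of -1.65 and of Aox3 of 1.83 in line number 2.

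The wild-type lines differed from each other by 3 genes, all higher in WT-2, of 16533 tested. Capn11 had 7.75 ± 0.821 CPM in WT-2 (SD, n = 3) against 1.44 ± 0.579 CPM in WT-1 (n = 2), and Wdfy1 36.0 ± 1.65 against 17.7 ± 0.764 CPM. The third, named after its values were seen, was X1700013H16Rik, with a log2 fold change of 3.93 (SE 0.46). At an unadjusted p under 0.05 there were 1258 genes, and DESeq2 called 40. Leaving out WT-1 replicate 1 or 2 gave 0 genes each, leaving out WT-1 replicate 3 gave 35, and leaving out any WT-2 library gave 2. With the replicate number as a block there were 6 genes, 5 higher and 1 lower.

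The mutant lines differed by 7 genes higher and 13 lower in Mut-2 than in Mut-1, and 8 of the 13 lay at the end of chromosome 5. Slc29a4 had 18.6 ± 2.01 CPM in Mut-2 against 48.7 ± 3.22 CPM in Mut-1 (SD, n = 3 libraries), Gtf3a 15.4 ± 2.51 against 36.1 ± 4.27 CPM, Rbak 13.8 ± 1.90 against 30.5 ± 3.12 CPM and Ap5z1 33.6 ± 4.15 against 73.8 ± 14.5 CPM, all on chromosome 5. Nxf3 was lower in Mut-2 by a log2 fold change of -2.34. Erdr1 and Wdfy1 were among the higher genes, with log2 fold changes of 1.94 and 1.05. The count was 1 without the 3 libraries of highest feeder share, which again leaves 1 Mut-2 library. Leaving out Mut-1 replicate 2, Mut-1 replicate 3 or Mut-2 replicate 2 gave 9, 3 and 2 genes, against 20. With the replicate number as a block there were 28 genes, 8 higher and 20 lower.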

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

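The tests of chromosomes, of the end of chromosome 5 and of the 2-cell list in this part were chosen after the result was seen, and the splits of libraries and lines before.

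The difference Mut-2 minus WT-2 was not the same as Mut-1 minus WT-1 for 12 genes in edgeR's test of the difference (adjusted p under 0.05). This test rests on single lines and technical replicates, so it cannot tell an effect of the mutation from a difference between lines. Among named genes these were Nxf3 (log2 difference -4.38), Slc29a4 (-1.55) and Uty (3.31). The median difference was -0.729 for the end of chromosome 5, -0.27 for the end of chromosome 10 and -0.161 for chromosome 8. These regions were chosen for their shifts in Mut-1 and in WT-2, so these values restate the shifts and are no separate test.

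Chromosome 14 genes were higher in both mutant lines. An effect limited to the neighbourhood of Tinf2 is argued against by 177 genes over 20 Mb from it, whose median shift was 0.33 in Mut-1 and 0.315 in Mut-2. More feeder RNA is argued against by the 3 mutant libraries whose feeder share lay in the wild-type range: the lowest of them was still 0.313 above the highest wild-type library. An additional copy of the chromosome in many mutant cells is a candidate explanation, since the lowest of the 10 bins in either mutant line was shifted by 0.202, but DNA copy number was not measured. Whether such a change would follow from the mutation, from the derivation of the lines or from culture was not tested.

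Genes at the end of chromosome 5 were higher in Mut-1 by a median of 0.735, with 74 of 74 genes higher, whereas genes before the break differed by 0.008. More feeder RNA is argued against by the 2 Mut-1 libraries with a feeder share in the wild-type range, which lay at least 0.724 above each library of the other lines. A gain of this segment in Mut-1 is a candidate explanation. It is not shared by Mut-2, so the genotype alone would not account for it.

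The 2-cell-stage list was higher in the mutants and lowest in WT-2. Reads shared between list members of 1 family, as the whole cause, are argued against by 9 members without a family member on the list. All 9 were higher, with a median log2 fold change of 1.097. Families were told by gene name alone, so reads shared with copies outside the list or under other names are not excluded. More feeder RNA is argued against by a median of 1.452 in the limma fit with the feeder share as a covariate, against 1.28 without it over the same 27 members. Whether low values in WT-2 alone account for the pattern cannot be told apart from an effect of genotype: both mutant lines were above WT-1 by medians of 0.485 and 0.852, but single mutant libraries lay within the WT-1 range (0.01 in Mut-1 replicate 1 and 0.21 in Mut-2 replicate 1, against 0.24 in WT-1 replicate 1). With 2 lines each the biological explanation, the genotype, stays open.

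Splits of 6 libraries into 3 and 3 are too few, at 10, for a share under 0.05. Mut-1 against WT-1 gave 34 genes, the real split alone (1 of 10) reaching that number, and the highest of the other splits 0. Mut-2 against WT-2 gave 76 genes (1 of 10) with a highest other of 0, and Mut-2 against Mut-1 20 genes (1 of 10) with a highest other of 7. WT-2 against WT-1 gave 3 genes and 2 of the 10 splits reached that number. The other one called 52 genes, and it set WT-1 replicates 1 and 2 with WT-2 replicate 2 against the rest, which points to a structure of the libraries other than the line. This split parts 1 of the 3 same-number pairs and the real split parts 3, as 3 of the other splits do, which gave 0 genes between the wild-type and between the mutant lines. In the limma fit, which in effect takes the 12 libraries as independent, the 3 splits of the 4 lines into pairs gave 233 genes for the genotypes (1 of 3) and at most 1 for the others, and 3 splits are too few as well.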

How the results depend on the processing

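Alternatives by chromosome, by feeder-rich library and with averaged WT-1 replicates were added after the data were seen, as were limma for Tinf2 and the feeder covariate for lists. The cause of a changed count was not tested. An alternative with fewer genes or samples also refits and readjusts the rest, so its change is not that of the removed part alone.

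The genotype count of 0 on line totals became 1 with RLE, 360 with DESeq2, 77 without a filter, 236 with 12 independent libraries, 233 with limma and line as a random block, 41 with the feeder covariate, 162 with line number as a block and 2 with WT-1 replicates averaged. Limma gave 15 without the 3 feeder-rich libraries, 13 of them among the 233, and 56 without chromosome 14 genes. Leaving out 1 line, which leaves 1 line of a genotype, gave 0 to 158 genes, and 1 library 0 to 96, the most without Mut-1 replicate 3 (11 without Mut-2 replicate 3).

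In the genotype comparison Tinf2 was lower under every alternative run, at -1.56 to -1.25. Its adjusted p was 0.0457 with RLE (-1.31), 3.97e-14 with DESeq2 (-1.31), 0.000112 with 12 libraries (-1.31), 9.89e-05 with limma (-1.31) and 0.0294 with WT-1 replicates averaged (-1.28). It was 0.532 without WT-2 and 0.161 without the feeder-rich libraries. The fold change was -1.34 to -1.25 with 1 line left out.

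In line number 1 the count of 34 became 183 without a filter, 81 with DESeq2, 54 without a fold minimum, 22 from 6 libraries, 12 with WT-1 replicates averaged, 5 without the shifted chromosome regions and 12 to 208 with 1 library left out. In line number 2 the count of 76 became 350, 209, 153 and 11 under the first 4 of these, 1 without the feeder-rich libraries and 9 to 81 with 1 library left out. Between wild-type lines 3 became 101 without a filter, 40 with DESeq2, 0 from 6 libraries, 1 with WT-1 replicates averaged and 0 to 35 with 1 library left out. Between mutant lines 20 became 99, 43, 43 without a fold minimum, 4 from 6 libraries, 1 without the feeder-rich libraries, 7 without the shifted regions and 2 to 24. The 4 shared genes became 7 without a fold minimum and 0 without the feeder-rich libraries.

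Of 28 lists 15 were called, 0 with an estimated correlation and 0 with fry (smallest adjusted p 0.079), and 11 to 18 under the others. The direction turned for oxidative phosphorylation with the feeder covariate (adjusted p = 0.776) and without the feeder-rich libraries (0.535), for Y-linked genes without WT-2 (0.00569) and for epidermal genes without Mut-1 (0.00749). With 1 line left out their adjusted p ran from 0.000165 to 0.568 and from 0.00749 to 0.755. The feeder share was higher in the mutants under all 3 alternatives. Of 4665 values of named genes and lists, 357 passed the threshold where the main fit had not, and 177 lost a call of the main fit. In 4 the direction turned with a call in the main fit or in the alternative, and 4127 did none of these. The last include values called in both fits, changes of sign without a call and DESeq2 values without an adjusted p.

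Over all lines, and within line numbers 1 and 2, replicate numbers were not taken to pair the libraries: of 18 same-number pairs 12 had correlated deviations over 0.1 (range -0.192 to 0.59). As a hint from the data, 10 of 12 libraries correlated best with one of their own number. With the replicate block the genotype count of 12 independent libraries was 288 and Tinf2 -1.33 (adjusted p = 1.22e-05), and the pairs gave 49 genes in line number 1, 139 in line number 2, 6 between wild-type and 28 between mutant lines. Depth was similar in all libraries. In simulation 40.0% of 2-fold changes between lines were recovered. These changes equalled the fold change minimum, so estimates just under it failed by rule, and this share does not measure power alone. Smaller changes are left out by the minimum unless their estimate exceeds it.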

Other observations

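The lists here were fixed before the data were examined, and the bins of chromosome 14 and the comparison of lists between line numbers were chosen after. Some gene groups differed in 1 line or in opposite ways in the mutant lines. Y-linked genes were lowest in WT-2 (median -0.92 relative to the mean of the lines, 5 genes) and highest in WT-1 (0.79), with -0.16 in Mut-1 and 0.43 in Mut-2. The test of the difference between line numbers gave this list an adjusted p of 0.00476 with an estimated correlation (camera, technical replicates). Epidermal genes had medians of 0.24 in Mut-1 and -0.17 in Mut-2, and the difference between line numbers had an adjusted p of 1.26e-05, but adjusted p = 0.121 with an estimated correlation. Senescence and apoptosis genes included Cxcl1 (49.3 ± 10.7 CPM in the mutants against 26.4 ± 2.91 in wild type, SD, n = 2 lines), whose log2 fold change in the limma fit was 0.84, and 0.27 with the feeder share as a covariate.

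The shift of chromosome 14 varied along its length in both mutant lines. In Mut-2 its bins starting at 10, 20 and 30 Mb lay at 0.27, 0.28 and 0.20 above wild type, and those starting at 50, 60 and 70 Mb at 0.51, 0.49 and 0.53. In Mut-1 the same bins lay at 0.34, 0.30 and 0.31 and at 0.37, 0.34 and 0.39. The bins starting at 40, 100, 110 and 120 Mb lay at 0.37, 0.42, 0.69 and 0.36 in Mut-1 and at 0.41, 0.44, 0.59 and 0.50 in Mut-2. The highest value of either line was that of the 10 genes in the bin starting at 110 Mb. Tinf2 lies in the bin that starts at 50 Mb.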
